A study of Homo sapiens with 6 samples.

How the data were processed

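RNA was measured by sequencing in PC9 cells, an established human lung adenocarcinoma cell line. The cells carried lentivirus with either a control shRNA (shCtrl) or shRNAs against both GATA6 and HOPX (shGata6Hopx). There were 3 libraries per group, and the groups were taken from the sample titles. Per the labels' protocols, all cells received doxycycline at 1 ug per ml for 5 days, and libraries were made from total RNA with a TruSeq kit and read as single ends of 50 bases. The strand setting of the counting is not given in the sources used here. Whether reads of overlapping loci on opposite strands were separated is therefore not known. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

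The data are 1 table of 34755 loci by 6 libraries. CASAVA, TopHat 1.4.1, HTSeq and edgeR, with genome build hg19, are named in the submitters' processing notes, and the table's own header gives no further step. The annotation the reads were counted on is not given in the sources used here. The deposited values are a normalised count signal: they are not whole numbers, and their totals differ little between the 6 libraries (46016376 to 50012498). Of the loci, 20239 have an identifier that starts with ucscCoding and 14516 have one that starts with XLOC. The table does not pair identifiers with gene symbols. In the reference name tables, 0 identifiers matched a gene ID or symbol of the gene name table, and 10 matched a RefSeq symbol or synonym, none of them with the ucscCoding prefix. One of these 10 named more than 1 gene, and assembly identifiers of this kind are numbered anew in each assembly, so no name was used. GATA6, HOPX and the 30 gene lists that had been fixed before the data were examined were therefore not analysed here, and the depletion of the targeted transcripts was not checked.

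The deposited values were examined for the reads behind them. Low values were not multiples of 1 step per library. They fitted a quantile adjustment to a common library size, in which each count is moved, within its group, from a negative binomial distribution at the library's own size to one at the common size. The relative library sizes and a common dispersion were estimated separately in each group from low loci. Both groups gave a dispersion of 0.0168. With these settings, 100% of the deposited values were returned from whole reads within a tolerance of 0.001. The tolerance was relative, except at the lowest values, where it was absolute. High values match under almost any settings, since rounding to a whole read moves them little. The 9049 loci without a read in any library match as well, so only the low values at other loci check the settings. On simulated tables made the same way, 100% of the reads were recovered. The whole reads sum to 45631557, 46294139 and 41635555 in shCtrl replicates 1, 2 and 3, and to 64669177, 50546193 and 42782280 in shGata6Hopx replicates 1, 2 and 3. The implied library sizes differ from these totals by factors between 0.964 and 1.05, so the deposited scaling used more than the total reads. Any interval from these reads covers counting error only. The recovered reads were used to state depth and in alternatives, and not in the main test.

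The main test was limma (version 3.58.1, R 4.3.3) on log2(value + 1), with a mean-variance trend in the variance shrinkage. It was two-sided, with Benjamini-Hochberg adjustment over all loci tested and a threshold of 0.05. Loci with a mean value of at least 10 over the 6 libraries were tested (15841 loci). All 6 libraries entered the fit, with the group as the only term. A fold change is on the log2(value + 1) scale, which understates the change of low loci. On simulated data with known changes over 15833 loci, the test recovered 83.7% of 98 loci changed by 2-fold and 99.0% of 98 loci changed by 4-fold. Of its 187 calls, 8 were false. In the simulation 200 loci were changed, loci varied independently, and all libraries had the same spread. The real libraries share deviations across loci, and shCtrl replicate 3 stands apart, so these rates need not hold for the real calls. Loci named in the text were chosen by a rule set before the data were examined. They are the loci with the largest rise or fall among those past the threshold, with the 3 values of one group all on one side of the other 3, and with a mean value at or above the median of tested loci. Since identifiers have no gene names, 2 loci are named in each direction. No gene coordinates were used.

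Alternative settings, set before the data were examined, changed the pseudocount (0.1 or 5), the filter (none, or a mean of at least 50), the scaling (TMM factors, median-of-ratios factors or quantile normalization), the variance model, the threshold and the libraries included, or added the replicate number as a block. The intended count models (edgeR and DESeq2) were not run, because the deposited values are not counts. A fit with voom on the recovered reads, a scaling by total reads alone, and a scaling of the recovered reads to the common size, with all reads and after thinning to 0.5 of the depth, were added after the data were seen. Tests of 3 libraries against 3 on a single value were exact permutation tests, whose smallest possible two-sided p is 0.1.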

Results

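The transcriptomes of PC9 lung adenocarcinoma cells were compared between 3 libraries with a control shRNA and 3 libraries with shRNAs against GATA6 and HOPX together. GATA6 is a zinc-finger transcription factor and HOPX is an atypical homeodomain protein, and both are expressed in the alveolar epithelium of the lung. Depth lay between 41635555 and 64669177 reads per library. A read was found at 25706 of the 34755 loci in at least 1 library. The 100 loci with the most reads took 19.7% ± 0.52 of the reads in shCtrl and 20.0% ± 0.71 in shGata6Hopx (SD, n = 3 each), a difference within the spread of the libraries (two-sided exact permutation test, p = 0.7, where 0.1 is the smallest the design allows).

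The first question was whether libraries of a group resembled each other more than those of the other group. The median absolute log2 difference over 15841 tested loci was between 0.12 and 0.28 in the 6 pairs of libraries within a group and between 0.20 and 0.33 in the 9 pairs between groups, so the ranges overlapped. No pair was a duplicate: within groups, the chi-square of the reads per degree of freedom lay between 11.2 and 87.5, where sampling noise alone gives 1. The first principal component held 45.8% of the variance between libraries and placed every shCtrl library on one side and every shGata6Hopx library on the other. The second held 30.5%, and on it shCtrl replicate 3 and shGata6Hopx replicate 2 lay far from shCtrl replicates 1 and 2. Among the controls, replicates 1 and 2 differed by a median of 0.12, while replicate 3 differed from them by 0.26 and 0.28. Control replicates 1 and 2 were thus nearer to every shGata6Hopx library (0.199 to 0.246) than to control replicate 3.

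**Figure D1:**
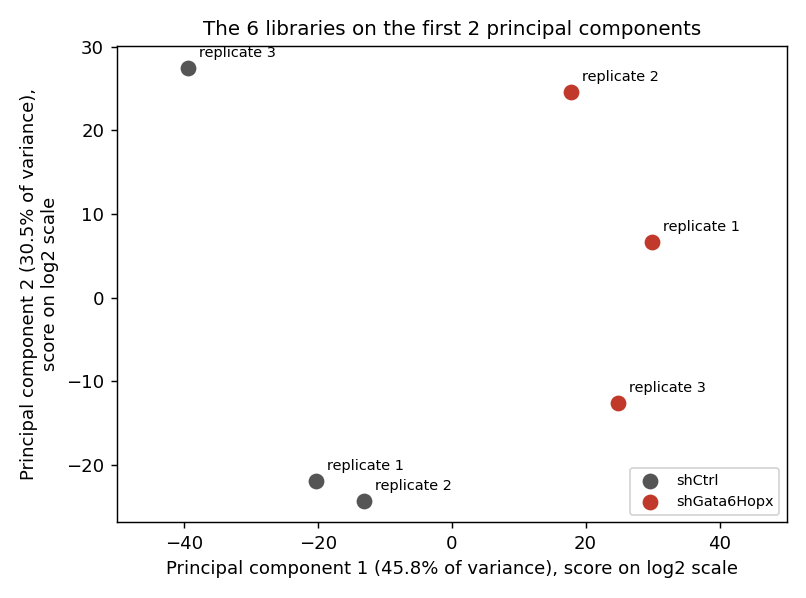
Scores of the 6 libraries on the first (45.8% of variance) and second (30.5%) principal components of log2(normalised count + 1) over 15841 loci, with 1 point per library coloured by group. The groups separate on the horizontal axis, and shCtrl replicate 3 lies 27.5 units above the centre of the vertical axis while shCtrl replicates 1 and 2 lie at -21.9 and -24.3.

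The second question was which transcripts differed in level when GATA6 and HOPX were targeted together. Of 15841 tested loci, 529 were higher and 621 were lower in shGata6Hopx, together 7.26% (limma, adjusted p under 0.05, n = 3 per group). Most of these differences were moderate. The median change was 0.71 on the log2 scale (1.64-fold) among the higher loci and -0.74 (1.68-fold) among the lower loci. At least 2-fold changes were found at 147 higher and 168 lower loci, and at least 4-fold changes at 13 higher and 23 lower loci. The median change over all tested loci was 0.003, and the median standard error was 0.14. At an unadjusted p under 0.05 there were 3690 loci. The groups did not overlap at 29.1% of tested loci, where chance gives 10% on average over splits of the libraries. Since loci vary together, a single split can lie far from that average, and the share in the other splits was not computed. At the 1150 called loci the groups never overlapped, which a test of 3 against 3 at this threshold nearly requires. The number of calls moved with single libraries. It was 284 without shCtrl replicate 1, 746 without shCtrl replicate 2, 1883 without shCtrl replicate 3, 269 without shGata6Hopx replicate 1, 425 without shGata6Hopx replicate 2 and 751 without shGata6Hopx replicate 3.

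**Figure D2:**
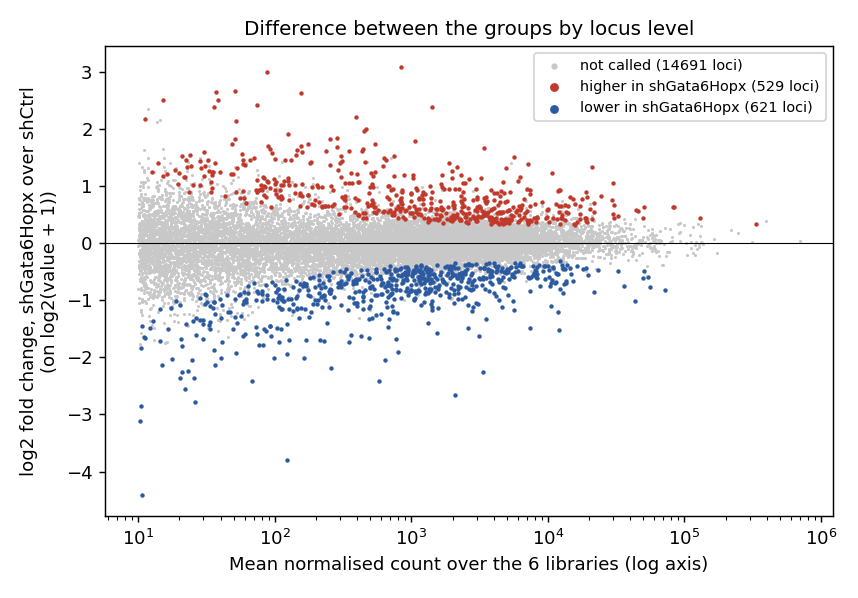
Log2 fold change of shGata6Hopx over shCtrl (on log2(value + 1)) against the mean normalised count over the 6 libraries on a log axis, 1 point per tested locus. The 529 higher loci (red) and 621 lower loci (blue) are spread over the whole range of levels, and the smallest change that is called shrinks as the level rises.

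Both directions were found at every level. When the loci were ranked by mean value and cut into 5 bins of equal size, in the lowest bin (mean values of 10.0 to 60.5), 52 loci were higher and 70 lower, and 105 of these changed by at least 2-fold. In the highest bin (3538 to 699903), 154 loci were higher and 119 lower, and 17 of these changed by at least 2-fold. The median standard error was 0.30 in the lowest bin and 0.10 in the highest, so a small change could be called only at the higher levels. By class of identifier, 488 of the 13401 tested loci with the ucscCoding prefix were higher and 583 were lower. Of the 2440 tested loci without this prefix, 41 were higher and 38 lower. The latter were expressed at a lower level, with a median value of 36.4 against 1260. Loci without the prefix took 1.02% ± 0.052 of the reads in shCtrl and 0.925% ± 0.054 in shGata6Hopx (SD, n = 3 each), a difference of -0.094 percentage points. This is larger than either SD, but the libraries of the 2 groups overlapped (two-sided exact permutation test, p = 0.2, where 0.1 is the smallest the design allows).

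Among loci at or above the median level, the largest rise was at ucscCodingXLOC_019436, which had a normalised count of 431 ± 97.0 in shCtrl and 2391 ± 1047 in shGata6Hopx (SD, n = 3 each). Its log2 fold change was 2.38 ± 0.34 (SE, limma adjusted p = 0.00651). The next was ucscCodingXLOC_017265, with 494 ± 192 in shCtrl and 1647 ± 356 in shGata6Hopx. Its log2 fold change was 1.79 ± 0.29 (SE, limma adjusted p = 0.0102), and without shGata6Hopx replicate 1 its adjusted p rose to 0.059. The largest fall was at ucscCodingXLOC_014879, from 3616 ± 2252 to 537 ± 212, a log2 fold change of -2.66 ± 0.42 (SE, limma adjusted p = 0.00959). The control spread at this locus came from shCtrl replicate 3 at 6215, with replicates 1 and 2 at 2240 and 2393, and without that library the log2 fold change was -2.19 (limma adjusted p = 0.00132). It was followed by ucscCodingXLOC_024784, from 5509 ± 1792 to 1133 ± 227, a log2 fold change of -2.25 ± 0.23 (SE, limma adjusted p = 0.00229). Reads at these 4 loci numbered at least 267 in every library, so counting error was small beside the spread between libraries. The table gives neither gene names nor positions for them.

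**Figure D3:**
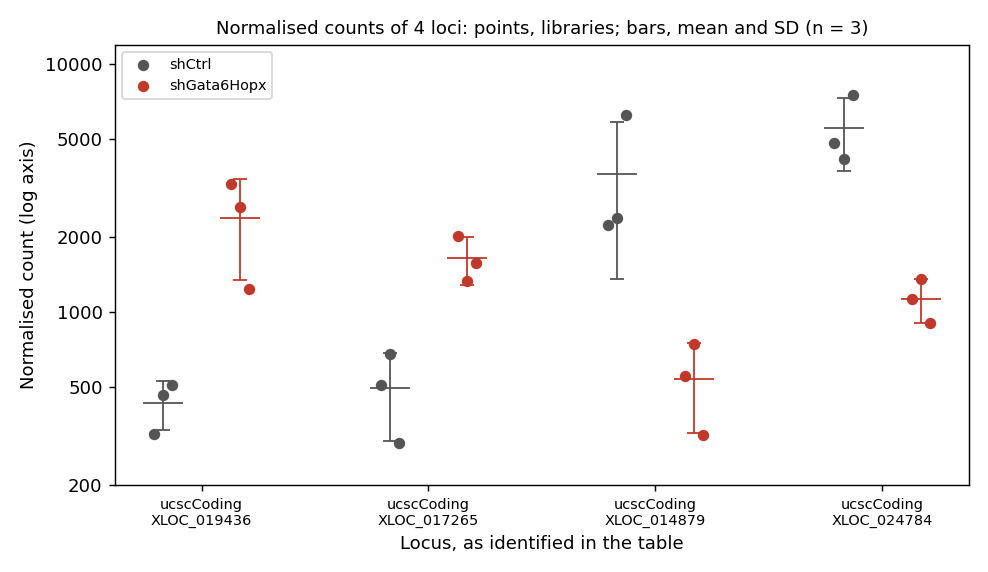
Normalised counts (log axis) of the 4 named loci in each library, with points for libraries and bars for the mean and SD of each group (n = 3). At ucscCodingXLOC_019436 and ucscCodingXLOC_017265 every shGata6Hopx library lies above every shCtrl library, and at ucscCodingXLOC_014879 and ucscCodingXLOC_024784 every one lies below.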

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

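The voom fit, the scaling by total reads alone, and the scaling of recovered reads to the common size with and without thinning were chosen after the data were seen; the other alternatives were planned. With all 6 libraries, the 529 higher and 621 lower loci stayed within 1.5 times under both other pseudocounts, both other filters, the 3 planned scalings, robust shrinkage, voom on the recovered reads (522 and 595) and scaling by total reads (451 and 682). Of the 1150 called loci, 1110 were also called by voom and 997 under scaling by total reads, which moved the median of all loci to -0.03. Without a mean-variance trend, 327 were higher and 424 lower. At an adjusted p under 0.01 there were 118 and 172, and with a 2-fold minimum 147 and 168. Leaving out 1 library gave between 103 and 936 higher and between 161 and 947 lower loci; the fewest came without shGata6Hopx replicate 1 (103 higher) and shCtrl replicate 1 (161 lower), and the most without shCtrl replicate 3. With the replicate block, 61 were higher and 67 lower. Numbering gives the block little basis. Across loci, deviations of same-numbered libraries from group means correlated at -0.06, -0.45 and -0.39 for replicates 1, 2 and 3. Matching shCtrl 1, 2 and 3 to shGata6Hopx 3, 1 and 2 gave 0.39, 0.25 and 0.57, but was not fitted. Under the block, adjusted p was 0.0517 for ucscCodingXLOC_019436 and ucscCodingXLOC_017265, 0.0676 for ucscCodingXLOC_014879 and 0.0373 for ucscCodingXLOC_024784. The causes of these changes in the number of calls were not tested. The number of libraries alone does not account for the fits without 1 library, since calls rose without shCtrl replicate 3. GATA6, HOPX and the gene lists gave no value under any setting, and edgeR and DESeq2 were not run. With the recovered reads scaled to the common size, thinning them once at random to 0.5 of the depth took the calls from 519 higher and 610 lower to 428 and 501; from the lowest to the highest of the 5 level bins, 67, 77, 47, 21 and 30 called loci were lost (57%, 29%, 18%, 10% and 11% of the calls there) and 12, 13, 5, 8 and 4 were gained.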

Other observations

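Tests of the ucscCoding prefix, and of shCtrl replicate 3 as a mixed library and after thinning to the smallest relative size, were chosen after the data were seen. So were the test of abundant loci in the form given here, including its scaling, and the range and spread of the covariances. The other tests here were set before their results were seen.

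Loci without the ucscCoding prefix were called less often than loci with it at the same level. Among them 3.24% were called, against 6.76% in random lists of prefixed loci matched on mean value (95% of 10000 lists between 5.82% and 7.75%). Changes of at least 2-fold, called or not, were seen at 3.48% of them and at 8.28% of the loci in a matched list (median over the lists). Their median log2 fold change was 0.03, above that of the matched lists (-0.06, 95% of lists between -0.085 and -0.042). Their share of all reads was lower in shGata6Hopx, so the median and the share differed in sign. A set test compared their direction with that of all other tested loci, not matched on level. It found no shift (camera, p = 0.574 with a preset correlation of 0.01 and p = 0.828 with an estimated correlation). These percentiles describe these libraries, since loci are not independent replicates.

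The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1150 loci and was the only 1 of the 10 with as many, and the highest of the others called 2. Each of the others puts libraries of both groups on each side. Any difference between the groups then adds to the spread within a side and lowers the calls. Their counts are therefore not a rate of calls to be had without a difference between the groups, and the comparison decides nothing about its cause.

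shCtrl replicate 3 stood apart from the other control libraries, and leaving it out raised the calls from 1150 to 1883. Read counting noise from its lower depth is argued against, because with every library thinned to the smallest relative size its median absolute log2 deviation from the other 2 libraries of its group was 0.268 over all tested loci, against at most 0.178 in the other libraries. A comparison with Poisson counting, set before, decides nothing, since every library exceeded it at 7510 loci with a mean value of at least 1000 (96.5 times in this library, 19.1 to 43.6 times in the others). The 100 loci with the most reads took 19.15% of its reads, below the range of the others (19.55% to 20.79%), but as the whole reason they are argued against, because leaving them out changed the deviation by a factor of 1.02, from 0.199 to 0.203, with both scaled by total reads. Set against the deviation under the deposited scaling, as first run, the factor was 0.916, which mixes in the change of scaling. A mixture with the other group as a whole would move a library only along the axis between the groups. As the whole reason it is argued against, because the part of the deviation off this axis was also larger than in the other libraries. The size of the off-axis part cannot show whether some mixture is present. The root mean square of this part over all tested loci was 0.45 on the log2 scale, against at most 0.33 in the other libraries. It cannot speak to a mixture with 1 shGata6Hopx library, which would also lie off the axis. Deviations from the group means correlated at 0.57 between this library and shGata6Hopx replicate 2. The part along the axis was 0.124 of its length at loci called without this library. A mixture cannot be told apart from ordinary spread there. In the other libraries, each at the loci called without it, this part lay between -0.015 and 0.206, though the loci differed by library. Over all tested loci it was 0.267 in shCtrl replicate 3, within the range of the others (0.022 to 0.336). At the 1150 loci called with all 6 libraries it was -0.082, the lowest of the 6, but those loci were chosen with this library in the fit. A thin background of reads over all loci may contribute: loci with a mean value under 10 took 523 RPM (reads scaled to the library total), the highest of the 6 libraries, followed by 504 in shGata6Hopx replicate 2, but the gain was 0.201 per such locus and 4.88 per locus in the lowest of the 5 tested level bins, and locus lengths were not used here. A difference between cultures or preparations stays open and was not tested.

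Loci with the ucscCoding prefix and consecutive identifier numbers tended to change together: the correlation was 0.123 over 8630 prefixed pairs and 0.033 over 612 pairs without the prefix, and the difference between the 2 classes was not tested. Over all 9242 consecutive pairs of tested loci the log2 fold changes correlated at 0.115 across loci, which are not independent replicates, against at most 0.033 in 1000 random orders within prefix and level; of 82 pairs with both loci called, 60 went the same way, while random orders gave on average 55.0 such pairs, of which 27.7 went the same way. Shared variation between libraries that is unrelated to the shRNAs may account for part or all of it, since differences between libraries of the same group gave correlations between 0.051 and 0.255. Covariance between consecutive loci was 0.017 ± 0.0024 (bootstrap SD) for the group difference; scaled to the group difference, that of the 6 differences within groups had a mean of 0.0072 and lay between 0.0011 and 0.021. No positions were used, so whether consecutive numbers mark neighbouring loci was not checked, and a response to the shRNAs was not tested apart from this variation.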
